A study of Mus musculus with 12 samples.

How the data were processed

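Bulk RNA of activated mouse CD8+ T cells was measured in 12 libraries, 3 for each combination of genotype (WT or Dock8 KO) and culture (media or collagen gel for 24 h). The labels give total RNA isolated with the PureLink kit, 150 ng of it per library, ribosomal RNA removal with RiboCop and library preparation with the KAPA HyperPrep kit. No DNase step is named in the labels. The deposited table holds 1 count per gene symbol and library, a raw count with no normalization. It held whole numbers, no columns for other samples, and 2 symbols that spreadsheet software had turned into dates.

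Per the submitters' processing notes, the tools were FastQC, MultiQC, HISAT2, SAMtools, Picard and featureCounts with the mouse genome GRCm38 (mm10); versions are not given. An aligner that allows splicing followed by counting over genes suits RNA-seq libraries of this kind. The annotation, the strand setting, and the handling of duplicate reads and of reads that map to several places are not given in the sources used here. Each could change a count: genes that share sequence, such as Hspa1a and Hspa1b or Entpd4 and Entpd4b, can lose or exchange reads, and overlapping genes on opposite strands can share them. Gene positions and types came from the GENCODE M21 annotation, which matched 96.2% of the symbols. Of the 55291 symbols, 15905 had no count in any library.

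Totals ran from 28483064 to 61390702 counts per library. Levels are given as CPM, the count times 1000000 over the scaled total of its library (unscaled for satellite-like loci). Replicates differed by more than counting noise, with a chi-square per degree of freedom of 13.5 to 172 across 18172 genes in pairs of replicates, so the test took its error from the spread between libraries and not from depth. Genes were kept by edgeR's filterByExpr with the groups given, which left 19010; the genes removed held 0.0437 to 0.104% of the counts of a library. Counts were scaled by TMM factors, and edgeR's quasi-likelihood F test with robust dispersion was fitted to the 4 groups at once, with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The contrasts were gel against media within each genotype, KO against WT within each culture, and the interaction of genotype and culture, 5 in all. Calls used a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors were the absolute log2 fold change divided by the square root of F. Log2 levels used a prior count of 2. The labels give n = 3 mice per group and do not state whether the media and gel libraries of a genotype share mice, so the replicate numbers were not used as pairs.

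Lists of genes were fixed in advance: DOCK8 partners and Hippo kinases, other DOCK family exchange factors, actin filament machinery, SRF and MRTF targets, YAP and TAZ targets, integrins and adhesion receptors, chemokine and egress receptors, matrix proteases and inhibitors, nuclear lamina and LINC complex, ESCRT membrane repair, p53 targets, DNA damage response and repair, interferon-stimulated genes, cytosolic DNA sensing and NF-κB targets, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, ATF4 targets, unfolded protein response and heat shock, antioxidant genes, S phase, G2 and M phase, ribosome biogenesis, cytotoxic effectors, cytokines, cytokine receptors and STAT5 feedback, naive and memory genes, tissue residency, inhibitory receptors and genes induced by the T cell receptor, apoptosis, TGF-β targets, markers of B cells, CD4 and regulatory T cells, macrophages and dendritic cells, NK and γδ T cells, neutrophils and mast cells, erythroid cells and platelets, and stromal cells, mitochondrially encoded transcripts, nuclear-retained and structured RNAs, and sex-linked transcripts. The 42 lists were tested in the 5 contrasts with limma's camera at a preset correlation of 0.01, adjusted over all 210 tests. With the correlation estimated from the data instead, 0 of the 75 calls held, by the same camera function. Calls within a list were also adjusted over the list alone.

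Genes named in the text were chosen by a rule: per contrast, the 6 largest rises and falls among called genes with a mean log2 CPM of at least 3 and, for pairs of groups, no overlap between libraries; the 3 smallest p in each direction; and up to 4 members per list in order of p. Dock8 and sex-linked transcripts were always given. Left out of the first parts were predicted gene models, pseudogenes, receptor segments, ribosomal protein genes and histones. Not every gene that the rule takes is named, and genes named outside it are marked as such.

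The test was checked on simulated data: 200 of the 19010 genes in WT media and gel libraries, all with a mean log2 CPM of at least 3, were changed by a known factor. It recovered 91% of those changed 1.5-fold, 97% at 2-fold and 100% at 4-fold, and 11 of 203 calls were false; recovery at lower levels was not measured. The list test called 2 of 2 changed lists and 0 of 40 unchanged ones, at the preset correlation. The simulated genes varied independently of each other, with no effect shared by the genes of a library. The simulation thus could not check the preset correlation, and recovery in the real data may be lower. In the real data the estimated correlation was 0.48 for S phase genes and 0.8 for oxidative phosphorylation (gel against media in WT).

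Alternatives were DESeq2 size factors, total counts alone, DESeq2's Wald test, limma-voom, no filter beyond 1 count, a stricter filter of 1 CPM in 6 libraries, a fit of the 6 libraries of a contrast alone, blocks by replicate number or assumed mouse, a 2-fold minimum, an adjusted p under 0.01, leaving out ribosomal RNA and mitochondrially encoded genes, list tests by fry or with an estimated correlation, and leaving out each library in turn. Added after the data were seen were a background subtraction, a fit without the libraries rich in ribosomal RNA, and a fit of genes with a mean log2 CPM of at least 3 only. Background per library was measured as reads per kb in the 1724 receptor genes of smell and pheromone sensing. Its source was tested in 15352 genes taken as silent from the other 9 libraries, 1271 of them receptor genes. No library was left out of the results as reported.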

Results

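RNA was sequenced from activated CD8+ T cells, the cytotoxic lymphocytes, taken from lymph node and spleen of WT and Dock8 KO mice, with n = 3 per group in the labels. Dock8 encodes a guanine nucleotide exchange factor that activates the small GTPase Cdc42, a regulator of actin assembly. After 3 days of activation and expansion the cells spent 24 h in media or embedded in bovine collagen at 2 mg/mL, a matrix through which T cells migrate. The series title relates Dock8 to an actin pool that preserves the shape of migrating T cells and shields their nucleus. The comparisons address which transcripts differed between gel and media in each genotype, between the genotypes in each culture, and whether the gel response itself differed between the genotypes. Each of the 4 groups held 3 libraries. The counts assigned to genes came to 53138362, 42001486 and 45841558 in WT media and 61390702, 40335274 and 40796920 in KO media. In gel they came to 36699062, 28483064 and 39710270 for WT and 37307525, 39223266 and 38392669 for KO. Of 55291 gene symbols, 19010 had enough counts to be tested.

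Dock8, on chromosome 19 (24999534 to 25202432), was lower in every KO library than in every WT library, as the genotype labels require. Its levels were 362, 418 and 442 CPM in WT media, 378, 410 and 449 in WT gel, 126, 109 and 125 in KO media, and 168, 161 and 158 in KO gel. The KO level was 29.4% of WT in media (log2 fold change −1.77, SE 0.09) and 39.3% in gel (−1.35, SE 0.09), with adjusted p 9.29e-08 and 8.44e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg correction. Gene-level counts cannot show whether the transcript left in the KO cells encodes protein. Within KO cells Dock8 was higher in gel (0.44, SE 0.09, adjusted p 0.00425). In WT cells the value was 0.02 (SE 0.09), and the difference between the genotypes did not pass the test (0.42, SE 0.13, adjusted p 0.0854). All 12 libraries came from male cells by their transcripts: Xist, which silences an X chromosome in females, had at most 15 counts, and the Y-linked Ddx3y lay between 65.3 and 89.2 CPM.

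**Figure D1:**
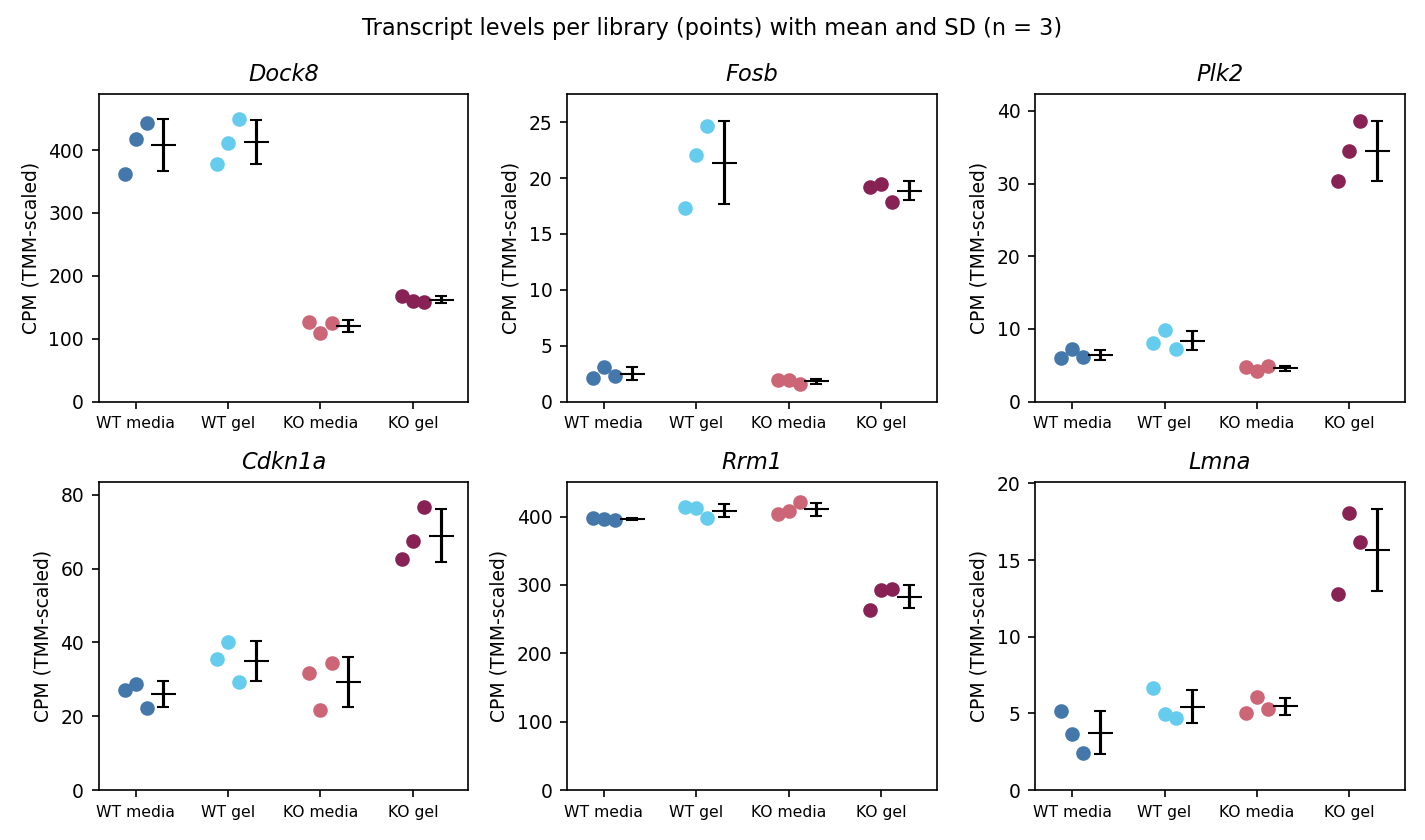
Levels of 6 transcripts in CPM for the 12 libraries (points, by group on the x axis) with the mean and SD of each group beside them (n = 3). Dock8 averaged 408 CPM in WT media and 120 CPM in KO media, Fosb was higher in gel than in media in both genotypes, and Plk2 was 7.48-fold higher in gel than in media in KO cells.

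The KO gel libraries differed from the other 9 in several library measures. At a common depth they held 27113 to 28478 genes with a count, against 23200 to 24281 in the others. Satellite-like loci, predicted gene models in repeats that are mostly silent, took 894 to 4730 CPM against 67.4 to 208. These loci were not among the library checks fixed in advance, so they may have been picked with the data in view. Mitochondrially encoded transcripts took 2.27 to 2.61% of counts against 1.34 to 2.31%, with an overlap in KO media. For genes at common depth, KO gel against KO media and KO gel against WT gel each gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 libraries against 3 can give. WT gel against WT media gave 0.1 too, in the opposite direction (ratio 0.978, against 1.16 in KO cells). Loci resembling ribosomal RNA took 18.6% of counts in WT gel library 2 and 12.3% in KO media library 3, above the other libraries. Transcripts abundant in other blood cells were low in KO gel, though not all at the WT gel level (in parentheses). Mean S100a8 of neutrophils was 0 CPM (0), Hbb-bs of erythroid cells 0.309 (0), Lyz2 of macrophages 0.243 (0.0502) and Igkc of B cells 0.261 (0.218). Some other markers were higher too, such as Itga2b of platelets at 9.53 (2.9) and Cd4 at 5.29 (2.39). The CD8 coreceptor genes Cd8a and Cd8b1 stood at 595 and 708 CPM in KO gel, and at 665 and 785 in WT gel.

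**Figure D2:**
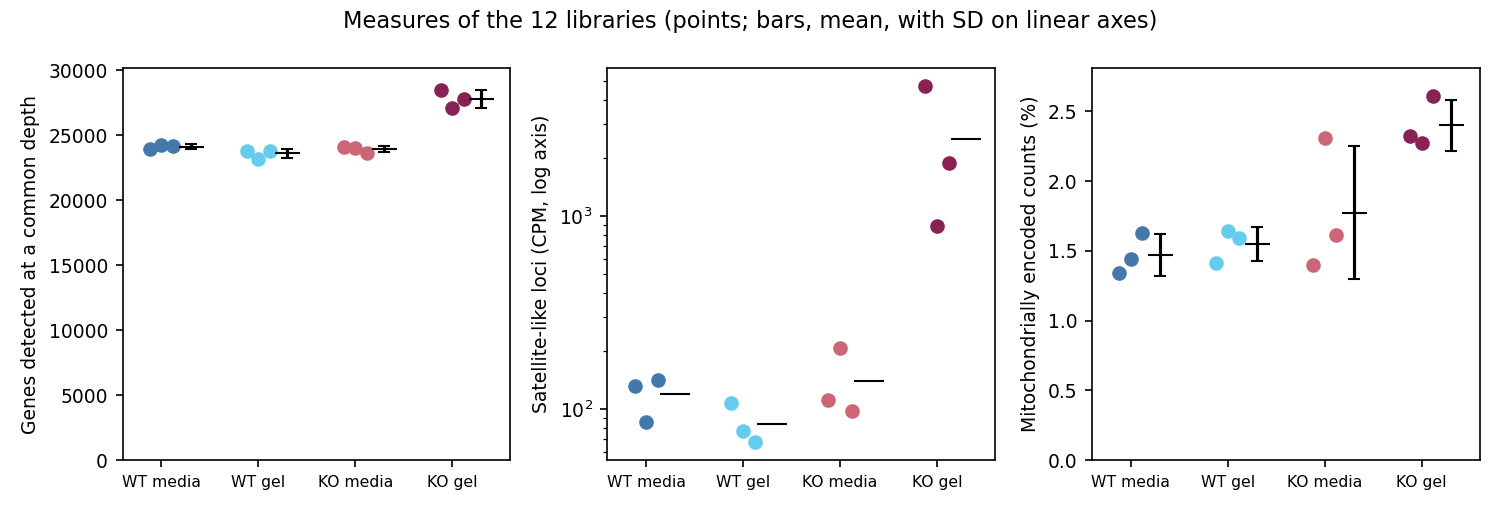
Genes detected at a common depth, satellite-like loci in CPM (log axis) and the percent of counts from mitochondrially encoded transcripts in the 12 libraries (points, by group on the x axis); bars give the group means, with SD on the linear axes. The 3 KO gel libraries held at least 27113 genes and at least 894 CPM of satellite-like loci, above all other libraries. The set of satellite-like loci was not among the library checks fixed in advance.

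In WT cells, 6 transcripts were higher and 1 lower in gel than in media, of the 19010 tested. Fosb and Fos, immediate early genes that encode AP-1 transcription factors, rose 8.52-fold (log2 3.09, SE 0.16) and 6.9-fold (2.79, SE 0.20), with n = 3 libraries per group and no overlap between the groups. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 1.74-fold (0.80, SE 0.08), and Osm, the cytokine oncostatin M, fell by 0.82 on the log2 scale (SE 0.09). The other called transcripts, named after their values were seen, were Klf4, a transcription factor gene of low level (0.533 CPM, SD 0.152, in media and 2.46 CPM, SD 0.81, in gel), and the gene models Gm37352 (1.45) and Gm26532 (1.28). Adjusted p for these 7 ran from 1.93e-07 to 0.00372 in edgeR's quasi-likelihood test with Benjamini-Hochberg correction. Without the test's correction 1033 genes had p under 0.05. Leaving out WT media library 1 raised the count to 16, and scaling by total counts alone gave 15 (7 higher, 8 lower). DESeq2's Wald test called 50 (25 higher, 25 lower), a fit with no filter beyond 1 count 195, and a fit of the 6 WT libraries alone 2. Blocks by assumed mouse, a pairing that the labels do not state, gave 171 (96 higher, 75 lower).

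Among gene lists fixed before the data were examined, interferon-stimulated genes, an antiviral program, lay lower in WT gel as a set (camera at its preset correlation, adjusted p 5.4e-10, and adjusted p = 0.259 with an estimated correlation). None of the 36 tested was called by edgeR over all genes, with 14 at an unadjusted p under 0.05, 0 called by limma-voom and 2 by DESeq2; adjusted over the list alone, 10 were lower. Irf7, a transcription factor gene of the interferon response, had −0.41 (adjusted p 0.315) in edgeR's test. The 15 chemokine and egress receptors lay higher as a set (camera adjusted p 0.000204; adjusted p = 0.259 with an estimated correlation), with Gpr183, an oxysterol receptor that guides lymphocyte positioning, at 0.40 and the CXCL12 receptor gene Cxcr4 at 0.23. edgeR called 0 of them, 5 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 1; adjusted over the list alone 4 were higher. With total counts as the scaling, their median moved from 0.07 to −0.02 with that of all genes, from −0.006 to −0.095, so the change of sign does not bear on their place among the other genes. The 31 p53 targets lay higher as a set (1.12e-06; adjusted p = 0.259 with an estimated correlation), with 0 called by edgeR, 7 at an unadjusted p under 0.05, 1 adjusted over the list alone, 0 by limma-voom and 1 by DESeq2. Camera also placed hypoxia genes (0.00299), CD4 and regulatory T cell markers (0.00389) and integrins (0.0118) higher in WT gel, with adjusted p = 0.671, 0.259 and 0.259 with an estimated correlation. ATF4 targets (0.00249), cholesterol synthesis (0.0071) and G2 and M genes (0.0426) lay lower, with adjusted p = 0.623, 0.698 and 0.717 with an estimated correlation. edgeR called 0 members of these 6 lists, and limma-voom 0; adjusted over the list alone 1 ATF4 target was lower and 1 CD4 marker higher, the same number as by DESeq2. In the order given, 2, 1, 1, 1, 1 and 1 had an unadjusted p under 0.05, and with total counts as the scaling the median of the integrins moved with that of all genes in the same way (0.07 to −0.02; camera 0.0781). Of the 22 targets of SRF and MRTF, transcription factors that respond to actin polymerization, 2 rose (Fosb and Fos), 0 fell and 20 were not called; adjusted over the list alone 3 were higher. Of 46 genes of the actin filament machinery, 30 of S phase and 20 of the nuclear lamina and its links to the cytoskeleton, edgeR, limma-voom and DESeq2 each called 0, with 0, 1 and 2 at an unadjusted p under 0.05, and 0 in each list adjusted over the list alone.

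In Dock8 KO cells, 2111 transcripts were higher and 1851 lower in gel than in media (3962 of 19010). Fosb rose 10.3-fold (log2 3.37, SE 0.16), Plk2, a polo-like kinase gene induced by p53, 7.48-fold (2.90, SE 0.13), and Cdkn1a, which encodes the cell cycle inhibitor p21, 2.35-fold (1.23, SE 0.16), with n = 3 libraries per group. Mcam, an adhesion molecule gene, rose by 3.28 (SE 0.13), and the inducible heat shock gene Hspa1a, which shares sequence with Hspa1b, by 4.10 (SE 0.18). Jun, which encodes an AP-1 partner of Fos, rose by 1.32 (SE 0.16), Plxna1, a semaphorin coreceptor gene, by 1.61 (SE 0.15), and Phlda3, a p53-induced inhibitor of AKT, by 1.19 (SE 0.13). Egr1, an immediate early gene, fell by 1.90 (SE 0.23), Cish, a feedback inhibitor of cytokine signalling, fell by 1.38 (SE 0.26), and Tnf, the inflammatory cytokine, fell by 0.95 (SE 0.12). Also lower were Prdx4, an endoplasmic reticulum peroxiredoxin gene (−0.91), Igfbp4 (−0.91), the lysosomal sulfatase gene Arsb (−0.90), Osm (−0.84) and the fatty acid desaturase gene Fads1 (−0.58). Adjusted p for the genes named ran up to 0.00491 (Cish) in edgeR's quasi-likelihood test with Benjamini-Hochberg correction, and 6982 genes had an unadjusted p under 0.05. The higher genes had a median fold of 1.9 and the lower ones 1.27, and 992 changed by at least 2-fold (969 higher, 23 lower). Of the higher genes 1472 had a mean log2 CPM below 3, of the lower ones 178. The count fell to 2050 without the libraries rich in ribosomal RNA, WT gel 2 and KO media 3, and to 2441 without KO media library 1, 2014 without KO gel library 1 and 2439 without KO gel library 3. It was 6063 with no filter beyond 1 count, 6190 in a fit of the 6 KO libraries alone and 7804 with blocks by assumed mouse.

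Genes of DNA replication and p53 targets moved in opposite directions in KO gel. Of 30 S phase genes, 29 fell and 0 rose (30 lower adjusted over the list alone). The thymidine kinase gene Tk1 fell by 0.60 (SE 0.07) and the ribonucleotide reductase gene Rrm1 fell by 0.54 (SE 0.06). As a set these genes had a camera adjusted p of 2.62e-23, and adjusted p = 0.259 with an estimated correlation. Of 30 G2 and M genes, 24 fell (26 adjusted over the list alone), among them Aurkb, the Aurora B kinase of the spindle checkpoint (−0.50). Camera gave 8.13e-13 for them, and adjusted p = 0.374 with an estimated correlation. With scaling by total counts alone, 29 S phase and 12 G2 and M genes were lower. Of 31 p53 targets, 20 rose, 1 fell and 10 were not called (23 higher and 1 lower adjusted over the list alone). They included Eda2r, a receptor gene of the TNF receptor family (3.12, SE 0.26), the nucleotide excision repair gene Ercc5 (0.66, SE 0.06) and Mdm2, the ubiquitin ligase that limits p53 (0.60, SE 0.06). For this list camera gave 2.59e-12, and adjusted p = 0.259 with an estimated correlation. Of 27 DNA damage response genes 2 rose and 11 fell (2 and 13 adjusted over the list alone), with Gadd45b at 0.77 and Nbn, a sensor of double-strand breaks, at −0.43. The set lay lower (camera 0.012, adjusted p = 0.443 with an estimated correlation).

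Of 36 interferon-stimulated genes, 10 rose, 1 fell and 25 were not called in KO gel (13 higher and 1 lower adjusted over the list alone). The chemokine gene Cxcl10 rose by 2.15 (SE 0.33), Ifit1 by 1.12 (SE 0.15) and Mx1 by 0.79 (SE 0.12). Camera gave an adjusted p of 0.00322, and adjusted p = 0.567 with an estimated correlation. Of 21 genes of cytosolic DNA sensing and NF-κB, 7 rose and 2 fell (10 and 2 adjusted over the list alone). Tnfaip3, which encodes the NF-κB inhibitor A20, rose by 1.06 (SE 0.08), while Tnf (−0.95) and the DNA sensor gene Cgas (−0.41) fell. The set lay higher (camera 0.0298, adjusted p = 0.637 with an estimated correlation). Of 25 cholesterol synthesis genes 14 fell and 0 rose (23 lower adjusted over the list alone), with the sterol carrier gene Stard4 at −0.57. Camera gave 9.8e-09 here, and adjusted p = 0.552 with an estimated correlation. Of 40 oxidative phosphorylation subunits 18 fell and 0 rose (26 lower adjusted over the list alone), with Cox5a, a subunit of cytochrome c oxidase, at −0.46. Camera gave 3.27e-09, and adjusted p = 0.612 with an estimated correlation.

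Of 46 actin filament genes in KO gel, 15 fell and 1 rose (18 and 2 adjusted over the list alone). The γ-actin gene Actg1 fell by 0.46 (SE 0.08), and the filament-severing cofilin gene Cfl1 (−0.33) and the crosslinker gene Flna (−0.26) were lower. As a set they lay lower (camera 1.45e-05, adjusted p = 0.259 with an estimated correlation). Scaled by total counts alone, 1 actin gene was higher and 1 lower (2 and 3 in a fit of only the genes with a mean log2 CPM of at least 3), and 2 of the oxidative phosphorylation subunits were lower. Of 20 lamina genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; camera 0.125). Lmna, which encodes the A-type lamins that stiffen the nucleus, rose by 1.52 (SE 0.22). The B-type lamin genes Lmnb1 and Lmnb2 were lower, at −0.33 (SE 0.06) and −0.37 (SE 0.08). SRF and MRTF targets went both ways, 4 higher and 7 lower of 22 (5 and 9 adjusted over the list alone; camera 0.331), and 3 higher and 2 lower in the fit restricted to genes with a mean log2 CPM of at least 3. Of 16 DOCK8 partners and Hippo kinases 0 rose and 1 fell, Was (−0.29, SE 0.08), which encodes the Wiskott-Aldrich syndrome protein. Adjusted over the list alone edgeR called 0 of them, 8 had an unadjusted p under 0.05, limma-voom called 1 and DESeq2 2. None of the 16 was lower by edgeR with total counts as the scaling or in that restricted fit, which called 1 higher.

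Beside the library measures above, mitochondrially encoded transcripts rose in KO gel in 5 of 15 (5 adjusted over the list alone), with the cytochrome oxidase subunit mt-Co2 at 0.55. Camera gave 0.000616, and adjusted p = 0.614 with an estimated correlation. Nuclear-retained or structured RNAs rose in 4 of 11 (5 adjusted over the list alone), with Neat1 at 1.02 (camera 0.0295, adjusted p = 0.442 with an estimated correlation). Scaling by total counts alone called 2007 genes higher and 869 lower (69.8% higher, against 53.3%). Of the 9959 genes with a mean log2 CPM of at least 3, 639 were higher and 1673 lower, and when fitted alone 1107 and 949.

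**Figure D3:**
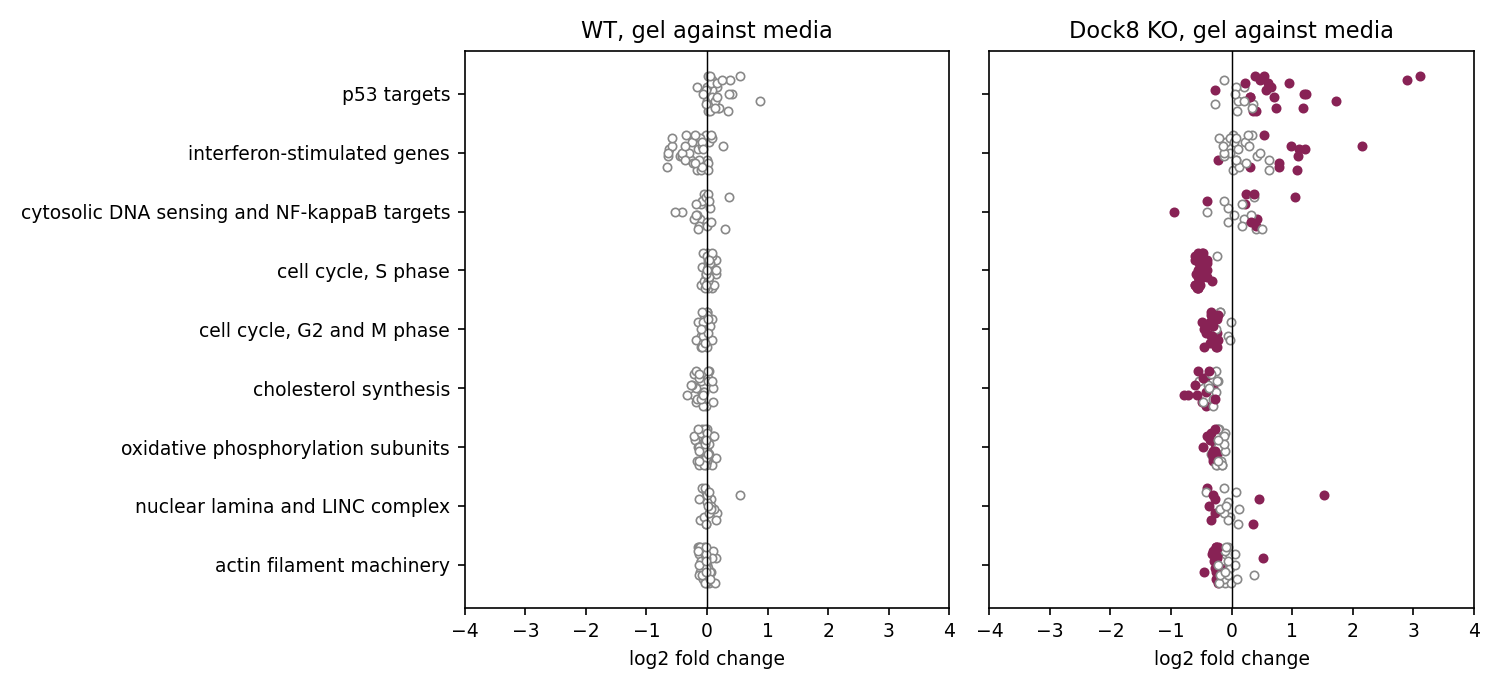
Log2 fold change of gel against media for the tested members of 9 gene lists in WT and in Dock8 KO cells; each point is 1 gene, filled where its adjusted p was under 0.05 in edgeR's quasi-likelihood test, and the vertical scatter within a list has no meaning. No member of these lists was called in WT cells; in KO cells 20 of 31 p53 targets were higher and 29 of 30 S phase genes lower.

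The gel responses of both genotypes shared the few WT calls. All 7 genes called in WT cells were called in KO cells in the same direction (6 higher and 1 lower, against 0.666 and 0.0974 expected were the calls independent). Across all 19010 genes the responses had a Pearson r of 0.135 (jackknife SE over libraries 0.186), and 0.192 across the 9959 genes with a mean log2 CPM of at least 3; genes are not independent replicates. The value rested on single libraries: r was 0.0405, 0.223 and 0.207 without WT media libraries 1, 2 and 3 and 0.0144 without WT gel library 3. It was 0.0107 with every gene that had a count.

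In media, without collagen, KO cells differed from WT cells in 36 transcripts (5 higher, 31 lower), Dock8 among them. Wdfy1, an adaptor gene of Toll-like receptor signalling on chromosome 1, was higher by 1.39 (SE 0.08), the endosomal GTPase gene Rab4a by 1.92 (SE 0.11), Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, by 1.23 (SE 0.07), the chemokine receptor gene Ccr2 by 0.67 (SE 0.09) and Hmgn5, a nucleosome-binding protein gene, by 0.33 (SE 0.06), with n = 3 libraries per group. Lower in KO were Erdr1 (−6.30, SE 0.19), which shares sequence with other loci, the neuritin gene Nrn1 (−0.94, SE 0.15), the cyclophilin gene Ppic (−0.84, SE 0.09), Synj2, a phosphoinositide phosphatase gene (−0.80, SE 0.08), and H2-Ob, an MHC class II chaperone gene (−0.71, SE 0.13). Adjusted p for these genes ran from 1.38e-10 to 0.0408 in edgeR's quasi-likelihood test with Benjamini-Hochberg correction. Of the 36, 8 lie between 69277601 and 69683286 on chromosome 14, among them Entpd4b (−0.85, SE 0.10), in a stretch of similar gene copies whose reads cannot be assigned with certainty. Of the lists, 1 of 15 chemokine receptors rose (Ccr2; 5 higher and 3 lower adjusted over the list alone; camera 0.143), and 1 of 33 apoptosis genes fell, Bmf (−0.71), which encodes a BH3-only death factor. Of 8 CD4 and regulatory T cell genes 1 was lower, Ikzf2 (−0.45, SE 0.08; 1 adjusted over the list alone; camera 0.143), which encodes the transcription factor Helios. edgeR called 0 of 46 actin filament, 31 p53 target, 30 S phase and 36 interferon-stimulated genes, with 4, 3, 0 and 7 at an unadjusted p under 0.05, 0 adjusted over each list alone, and 0 by limma-voom and by DESeq2. Over all genes 1423 had an unadjusted p under 0.05. The count was 69 without WT media library 1, 23 without KO media library 2, and 19 without both libraries rich in ribosomal RNA. DESeq2's Wald test called 89, and a fit with no filter beyond 1 count 435.

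In gel, KO and WT cells differed in 2819 transcripts (1354 higher, 1465 lower in KO; n = 3 libraries per group). Plk2 was higher by 2.05 (SE 0.13), Cdkn1a by 0.99 (SE 0.16), Rgs1, a regulator of G protein signalling that dampens chemokine responses, by 1.03 (SE 0.09), Plxna1 by 1.18 (SE 0.15), Mcam by 2.71 (SE 0.13) and Hspa1a by 3.22 (SE 0.17). Wdfy1 (1.29), Nnt (1.03), Rab4a (1.86) and Erdr1 (−5.99) differed as in media; of the 36 genes called in media 28 were called in gel in the same direction. Lower in KO were Lrrc32, which encodes the TGF-β docking receptor GARP (−1.36, SE 0.17), Egr1 (−1.30, SE 0.23), Myadm (−0.90, SE 0.16), Tmem254a (−1.61, SE 0.40) and Fads1 (−0.64, SE 0.06). Adjusted p for the named genes ran up to 0.0248 (Tmem254a) in edgeR's quasi-likelihood test with Benjamini-Hochberg correction, and 5715 genes had an unadjusted p under 0.05. At least a 2-fold difference was seen in 717 (684 higher, 33 lower). The count was 1740 without WT gel library 2, 1485, 1716 and 1804 without KO gel libraries 1, 2 and 3, and 1358 without both libraries rich in ribosomal RNA.

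All 30 S phase genes were lower in KO gel than in WT gel by edgeR's test (30 adjusted over the list alone), with the replication licensing genes Cdc6 and Cdt1 at −0.66 and −0.71. Camera gave 3.42e-26, and adjusted p = 0.259 with an estimated correlation. Of 30 G2 and M genes 26 were lower (27 adjusted over the list alone; camera 9.06e-18, adjusted p = 0.259 with an estimated correlation). Of 31 p53 targets 16 were higher and 1 lower (18 and 1 adjusted over the list alone), with Perp, which encodes a desmosome protein, at 1.34. Camera gave 1.34e-08, and adjusted p = 0.259 with an estimated correlation. Of 36 interferon-stimulated genes 17 were higher and 1 lower (21 and 1 adjusted over the list alone), with Ifit1 at 1.69 and Mx1 at 0.93. Camera gave 6.98e-07, and adjusted p = 0.259 with an estimated correlation. Of 30 targets of ATF4, the transcription factor of the integrated stress response, 10 were higher and 1 lower (12 and 2 adjusted over the list alone), with Chac1 at 1.78 and Ddit3 at 0.63. Camera gave 0.00715, and adjusted p = 0.637 with an estimated correlation.

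Integrins and adhesion receptors were lower in KO gel than in WT gel in 8 of 26 and higher in 1 (8 and 1 adjusted over the list alone). Itga4 stood at −0.48 and Itgb7, its partner in the gut-homing integrin, at −0.34. The set lay lower (camera 0.00449, adjusted p = 0.259 with an estimated correlation). Chemokine receptors were lower in 3 of 15 (5 adjusted over the list alone; camera 0.143): Cxcr4 −0.38, the lymph node homing receptor gene Ccr7 −0.38 and S1pr4 −0.36. Of 46 actin filament genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with Gsn, which encodes the filament-severing gelsolin, at −0.46. Camera gave 0.00322, and adjusted p = 0.442 with an estimated correlation. Scaled by total counts alone, 1 actin gene was lower and 2 higher, and the list's median moved from −0.09 to 0.01. Of 20 lamina genes 5 were lower and 1 higher (10 and 1 adjusted over the list alone): Lmna stood at 1.52, Lmnb2 at −0.45 and Lbr, the lamin B receptor gene, at −0.33. The set lay lower (camera 0.039, adjusted p = 0.259 with an estimated correlation). Of 18 glycolysis enzymes 5 were lower and 0 higher (5 lower adjusted over the list alone), with the lactate exporter gene Slc16a3 at −0.86. Camera gave 0.000752, and adjusted p = 0.637 with an estimated correlation. Mitochondrially encoded transcripts were higher in 6 of 15 (9 adjusted over the list alone), with mt-Co2 at 0.64. Camera gave 4.05e-06, and adjusted p = 0.567 with an estimated correlation. Cholesterol synthesis genes were lower in 7 of 25 (8 adjusted over the list alone; camera 0.000514, adjusted p = 0.637 with an estimated correlation), 0 of them by edgeR with total counts as the scaling. Oxidative phosphorylation subunits were lower in 1 of 40 (1 adjusted over the list alone; camera 0.000144, adjusted p = 0.698 with an estimated correlation). DNA damage response genes were higher in 2 and lower in 8 of 27 (4 and 10 adjusted over the list alone; camera 0.0298, adjusted p = 0.552 with an estimated correlation). NF-κB and DNA sensing genes were higher in 5 and lower in 2 of 21 (6 and 3 adjusted over the list alone; camera 0.0404, adjusted p = 0.637 with an estimated correlation). Nuclear-retained RNAs were higher in 5 of 11 (7 adjusted over the list alone; camera 0.0042, adjusted p = 0.286 with an estimated correlation). Markers of other cell types, most of them with few reads, were higher in 6 of 6 neutrophil and mast cell genes (6 adjusted over the list alone; camera 6.1e-06, adjusted p = 0.259 with an estimated correlation). They were also higher in 6 of 10 erythroid and platelet genes (7 adjusted over the list alone; camera 4.88e-05, adjusted p = 0.259 with an estimated correlation) and in 4 of 11 B cell genes (5 higher and 2 lower adjusted over the list alone; camera 0.152). Scaled by total counts alone, the median of all genes stood at 0.102 and 1875 genes were higher and 407 lower (82.2% higher, against 48%); 22 S phase and 7 G2 and M genes were then lower. Of the 9959 genes with a mean log2 CPM of at least 3, 401 were higher and 1325 lower, and when fitted alone 776 and 736.

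The gel response differed between genotypes for 636 transcripts by the interaction of genotype and culture, 360 with a higher and 276 with a lower response in KO cells (n = 3 libraries in each of the 4 groups). The responses of Plk2 (2.53, SE 0.18), Mcam (2.90, SE 0.19), Hspa1b (3.64, SE 0.30) and Jun (1.55, SE 0.23) were higher in KO cells, as were those of the long noncoding RNAs Kcnq1ot1 (1.35, SE 0.25), Lncpint, which p53 induces (1.17, SE 0.21), and Neat1, the scaffold of nuclear paraspeckles (1.13, SE 0.19), and of the interferon-stimulated Rtp4 (1.12, SE 0.24). Kcnq1ot1 lies antisense to Kcnq1, and the strand setting of the counting was not given. Lower were the responses of Egr1 (−2.15, SE 0.32), Prdx4 (−0.90, SE 0.15), Cd93 (−0.85, SE 0.17), Scd2, a stearoyl-CoA desaturase gene (−0.82, SE 0.19), and the DNA repair and licensing genes Rad54l and Cdc6 (both −0.65, SE 0.09). These genes were chosen among those with adjusted p under the threshold of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg correction; 3726 genes had an unadjusted p under 0.05. The count moved with single libraries: it was 1959 without WT media library 1, 178 and 337 without WT media libraries 2 and 3, 257 and 309 without KO media libraries 1 and 3, 324 and 262 without WT gel libraries 1 and 2, and 211, 286 and 277 without KO gel libraries 1, 2 and 3. It was 29 (28 higher, 1 lower) without both libraries rich in ribosomal RNA, 263 with at least a 2-fold difference (260 higher, 3 lower), 366 with the stricter filter, 1149 by DESeq2's Wald test and 1768 with no filter beyond 1 count. Blocks by replicate number gave 962 and blocks by assumed mouse 3431.

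The gel response was lower in KO cells for 24 of 30 S phase genes (30 adjusted over the list alone), among them the genes Cdc6 and Tk1 (both −0.65). Without both libraries rich in ribosomal RNA 1 lower response was called among all genes, so at most 1 of these 24 S phase calls was kept. Camera gave 6.06e-28, and adjusted p = 0.259 with an estimated correlation. It was lower for 4 of 30 G2 and M genes (19 adjusted over the list alone; camera 3.9e-11, adjusted p = 0.417 with an estimated correlation). It was higher for 10 of 31 p53 targets (15 higher and 1 lower adjusted over the list alone; camera 5.4e-09, adjusted p = 0.259 with an estimated correlation). Of 36 interferon-stimulated genes 7 had a higher response, Ifit1 by 1.75 (16 adjusted over the list alone). Camera gave 5.4e-09, and adjusted p = 0.259 with an estimated correlation. The chemokine receptors Ccr2 (−0.59), Cxcr4 (−0.41) and Cxcr6 (−0.45) had lower responses, 3 of 15 (3 adjusted over the list alone; camera 0.0151, adjusted p = 0.259 with an estimated correlation). So had 2 of 20 lamina genes, Emd and Lmnb2 (3 higher and 7 lower adjusted over the list alone; camera 0.0438, adjusted p = 0.27 with an estimated correlation). Of 46 actin filament genes edgeR called 0, with 7 at an unadjusted p under 0.05, 0 adjusted over the list alone, 0 by limma-voom and 3 lower by DESeq2. Camera gave 0.000807, and adjusted p = 0.374 with an estimated correlation. Scaled by total counts alone the median of all genes stood at 0.124, and 458 responses were higher and 24 lower (95% higher, against 56.6%), with 4 S phase and 0 G2 and M genes lower by edgeR. Of the 9959 genes with a mean log2 CPM of at least 3, 103 responses were higher and 265 lower, and when fitted alone 125 and 123.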

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

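The tests of sequence shared between X-linked genes and of the stronger background subtraction, and the values without the libraries rich in ribosomal RNA and with background subtracted, were chosen after the results were seen. The results here stand out because the gel response of Dock8 KO cells differed from that of WT cells, by the test of that difference itself (the interaction, edgeR's quasi-likelihood test with Benjamini-Hochberg correction).

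Between the genotypes 636 of 19010 responses differed (3.35%). Among the 120 tested genes named in the text 51 did. That larger share follows from the naming rule, which took genes in part by their calls in this same contrast, and adds no support. The response was higher in KO cells for 10 of 31 p53 targets (log2 differences: Plk2 2.53, Eda2r 2.58, Perp 0.97, Phlda3 0.83, Ercc5 0.65, Pmaip1 0.57, Mdm2 0.53). It was lower for 24 of 30 S phase genes (Cdt1 −0.74, Cdc6 −0.65, Tk1 −0.65, Rrm1 −0.58) and 4 of 30 G2 and M genes (Aurkb −0.45), and with total counts as the scaling for 4 and, by edgeR, 0 of them. Without the libraries rich in ribosomal RNA 1 lower response was called among all genes, so at most 1 of these cell cycle calls was kept. The response was higher for 7 of 36 interferon-stimulated genes (Ifit1 1.75, Rtp4 1.12, Mx1 0.77), with 29 not called, and for 4 of 21 NF-κB and DNA sensing genes (Tnfaip3 0.69, Icam1 0.53), with 17 not called. Among the remaining genes, higher values were those of Hspa1b 3.64, Hspa1a 3.42, Mcam 2.90, Csf1 1.72, Jun 1.55, Cd74 1.41, Kcnq1ot1 1.35, Itga2b 1.30, Lncpint 1.17, Neat1 1.13, Plxna1 1.10, Rgs1 0.93, Ddit3 0.76, Gadd45b 0.64 and Ikzf2 0.48. As a list, heat shock and unfolded protein genes were not called (camera 0.103). Lower values were those of Egr1 −2.15, Prdx4 −0.90, Cd93 −0.85, Scd2 −0.82, Arsb −0.81, Rad54l −0.65, Fads1 −0.64, Ccr2 −0.59, Dusp6 −0.59, Nkg7 −0.57, Npm1 −0.57, Hspa8 −0.53, Cxcr6 −0.45, Lmnb2 −0.44, Emd −0.43, Hmgn5 −0.42, Cxcr4 −0.41, Adam19 −0.41 and Nbn −0.39.

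Of the lists, 18 differed by camera at its preset correlation. Responses were lower in KO cells for S phase (6.06e-28), G2 and M (3.9e-11), oxidative phosphorylation (1.26e-06), cholesterol synthesis (9.29e-06), glycolysis (0.000137), actin filament machinery (0.000807), DNA damage response (0.00703), chemokine receptors (0.0151), hypoxia (0.0225), lamina (0.0438) and ribosome biogenesis (0.0494). They were higher for p53 targets (5.4e-09), interferon-stimulated genes (5.4e-09), erythroid (0.000876) and neutrophil markers (0.0121), NF-κB targets (0.00305), nuclear-retained RNAs (0.00648) and mitochondrially encoded transcripts (0.0198). With an estimated correlation the adjusted p of these lists lay between 0.259 and 0.77. Scaled by total counts alone the median of the actin list moved from −0.11 to 0.01, and that of ribosome biogenesis from −0.11 to 0.02. The median of all genes moved from 0 to 0.124, so both lists stayed below it. These lists hold abundant genes, with a median log2 CPM of 8.23 and 5.79. The median of the 9959 genes with a mean log2 CPM of at least 3 moved from −0.073 to 0.053, closer to both lists. Part of the gap to all genes thus goes with expression level.

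A first pattern is the larger number of genes detected in the KO gel libraries, with depth argued against, since at a common depth the lowest KO gel library exceeded the highest other library by 2832 genes. Genes silent in T cells should hold background only. Their reads per kb on X against autosomes in these male cells had a ratio of 0.527 (95% bootstrap interval 0.453 to 0.613). That is near the dosage of a single X copy, as genomic DNA would give. Transcription in proportion to gene copies would give it too. Silent genes on the single Y chromosome had 0.25 reads per kb, against 0.339 on X and 0.644 on autosomes. Whether sequence shared among the Y-linked genes lowered their value was not checked, so it cannot decide for or against DNA. Shared sequence among X-linked genes is argued against by the ratio of 0.501 (0.411 to 0.603) in genes of unique sequence. Silent receptor genes had 0.365 reads per kb against 0.643 in other silent genes. An even DNA source alone would give like densities only at the same copy number and with equally unique sequence. The other silent genes included those on X and Y, and sequence shared among receptor genes was not checked. The difference thus cannot argue against DNA. Silent receptor genes also had 0.353 (0.285 to 0.456) of the density of silent genes inside expressed genes, with the same limit of shared sequence. DNA, unspliced RNA and transcription of silent loci thus cannot be told apart by these values. An effect of Dock8 loss in collagen on silent loci, or on how cells and DNA were recovered from the gel, was not tested. The background is confounded with the group.

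A second pattern is the 3962 calls in KO gel against media. An even genomic DNA background is argued against as the cause of the higher calls. After its subtraction 95.7% of the higher genes were still called higher, and the estimated background in them had a median of 0.731%. After subtraction at the density of silent genes inside expressed genes 93.3% were (635 of 639 with a mean log2 CPM of at least 3). Of the lower genes 95.9% were still called lower, which cannot decide the question for them. Scaled to depth, reads per kb in receptor genes were 2.57 times as high in KO gel as in KO media. Subtraction thus took more from KO gel and could only move lower genes further down, apart from rescaling. Another candidate cause, the libraries rich in ribosomal RNA, was not excluded as a contributor: without them, and so with fewer libraries, 2050 genes were called, while leaving out the ribosomal RNA and mitochondrially encoded genes themselves gave 4152 calls and kept 98.2% of the 3962. The regroupings of the libraries, 10 per pair of groups, are too few for a share under 0.05: for KO gel 1 split gave as many calls (3962; highest other 0), and for KO against WT in gel 1 (2819; highest other 0). A response of Dock8 KO cells to collagen stays open as untested against these.

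For the interaction count, 9 of 100 splits of the libraries, the real one included, gave at least as many calls as the real 636 (highest other 2828), a share that leaves chance open by this count. It is a weak measure of chance, since all 8 others as large were among the 14 other splits that kept both gel groups intact and so held the difference between them. The splits that mixed the gel groups gave at most 0 calls by edgeR (median 0). Without the libraries rich in ribosomal RNA the count was 29 (28 higher, 1 lower). For gel against media in WT, 2 of 10 splits gave as many calls as the real 7 (highest other 1258), too few splits for a share under 0.05. The split with 1258 calls, which set WT media 1, WT gel 1 and WT gel 2 against the rest, points to a structure among the WT libraries. Deviations from group means correlated at 0.42 between WT media 1 and WT gel 1, and at 0.51 between WT media 3 and WT gel 3. The crossed pairs stood at −0.46 (WT media 1, WT gel 3) and −0.42 (WT media 3, WT gel 1). The structure thus followed the replicate number in part, with 0.056 between WT media 2 and WT gel 2. Blocks by assumed mouse gave 171 calls in WT.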

How the results depend on the processing

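The values with background subtracted, without the libraries rich in ribosomal RNA, and for genes with a mean log2 CPM of at least 3 only were chosen after the results were seen. Over the settings compared gene by gene, which leave out the 2-fold minimum, the adjusted p under 0.01 and the fit of genes with a mean log2 CPM of at least 3, 7811 values of named genes kept their direction and side of the threshold and 947 fell below it; 0 reversed by edgeR or the other tools. Values of lists kept both in 1506 cases and fell below in 249. All these genes and lists were called in the main fit and refitted on the same libraries, so reversals were unlikely from the start. Of all 636 interaction calls, 28% (without WT media 2) to 97.6% (without WT media 1) were kept with 1 library left out. Without both libraries rich in ribosomal RNA 4.56% were. Calls in the order gel against media in WT, gel against media in KO, KO against WT in media, KO against WT in gel, and interaction were 7, 3962, 36, 2819 and 636. With total counts alone WT gave 15. DESeq2's Wald test gave 50 in WT, 89 in media and 1149 for the interaction. With no filter beyond 1 count there were 195, 6063, 435 and 1768 (WT, KO, media, interaction), and 366 for the interaction with the stricter filter. Fits of 6 libraries alone gave 2 in WT and 6190 in KO. Blocks by replicate number gave 57 in media and 962 for the interaction, and blocks by assumed mouse 171, 7804 and 3431 (WT, KO, interaction). A 2-fold minimum left 992, 21, 717 and 263 (KO, media, gel, interaction), and an adjusted p under 0.01 left 1650, 1163 and 70 (KO, gel, interaction); both remove calls by construction. Without the libraries rich in ribosomal RNA there were 2050, 19, 1358 and 29, with fewer libraries. Genes with a mean log2 CPM of at least 3 only gave 4, 2056, 19, 1512 and 248 of 9959 genes. Apart from the settings that drop genes or libraries, the cause was not tested. Of 210 list tests 75 were called, 0 with an estimated correlation, and 45 by the directional and 111 by the mixed form of fry, which tests another hypothesis. Leaving out 1 library at a time gave 7 to 16, 2014 to 5243, 23 to 69, 1485 to 3735 and 178 to 1959 calls, 69 to 91 lists, an agreement of the gel responses of 0.0144 to 0.223, and Dock8 at −1.84 to −1.70 in media and −1.41 to −1.28 in gel. Single libraries moved a count by over 1.5 times: WT media 1 for gel in WT (16), in media (69) and for the interaction (1959); WT media 2 and 3 for the interaction (178, 337); KO media 1 for gel in KO (2441) and the interaction (257); KO media 2 in media (23); KO media 3 for the interaction (309); WT gel 1 for the interaction (324); WT gel 2 in gel (1740) and the interaction (262); KO gel 1, 2 and 3 in gel (1485, 1716, 1804) and the interaction (211, 286, 277), and KO gel 1 and 3 for gel in KO (2014, 2439). For 10 of 12 libraries the closest library of the other culture within the genotype bore the same number, a hint that numbers mark mice; correlations of same numbers ran from 0.056 to 0.51 against a threshold of 0.1, so the numbers were not used as pairs. Calls were not refitted at matched depth.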

Other observations

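The values without the libraries rich in ribosomal RNA and in a fit of genes with a mean log2 CPM of at least 3 were chosen after the results were seen; the lists and the other tests were fixed earlier. Members of further lists were called in both directions. Over all 19010 genes tested, 20.8% were called in KO gel against media and 14.8% in KO against WT in gel. A count of called members near that share is no result about a list, here and in the lists that follow. In KO gel against media (edgeR's quasi-likelihood test over all genes), residency genes rose in 4 of 20 and fell in 4 (4 and 4 adjusted over the list alone), with the G protein signalling regulators Rgs1 and Rgs2 at 1.00 and 1.29 and Dusp6, a phosphatase of ERK, at −0.79. Cytotoxic effectors rose in 2 of 26 and fell in 4 (2 and 7 adjusted over the list alone): Nkg7, a granule protein gene, −0.40, and Tbx21, which encodes T-bet, −0.39; in KO gel against WT gel 3 were higher and 2 lower (4 and 5 adjusted over the list alone), with Ifng at 1.29. Cytokines rose in 2 of 20 and fell in 2 (2 and 2 adjusted over the list alone), with the OX40 ligand gene Tnfsf4 at 1.59 and Csf1 at 1.20. Matrix proteases and inhibitors rose in 4 of 18 and fell in 2 (5 and 4 adjusted over the list alone; Plaur, the urokinase receptor gene, 0.51, Adam19 −0.27), integrins in 3 of 26 with 3 lower (3 and 6 adjusted over the list alone; Icam1 0.41, Itgb1 −0.42), and chemokine receptors in 2 of 15 with 4 lower (3 and 5 adjusted over the list alone; Ccr2 −0.53, S1pr1 0.30). Antioxidant genes rose in 6 of 22 and fell in 1 (6 and 2 adjusted over the list alone; the quinone reductase gene Nqo1 0.89), ATF4 targets in 6 of 30 with 4 lower (6 and 5 adjusted over the list alone), and apoptosis genes in 4 of 33 with 6 lower (5 and 6 adjusted over the list alone; the BH3-only gene Pmaip1 0.56, Bcl2 −0.42; 7 higher and 3 lower in a fit of only the genes with a mean log2 CPM of at least 3). Heat shock and unfolded protein genes rose in 2 of 24 and fell in 8 (2 and 11 adjusted over the list alone; the constitutive chaperone gene Hspa8 −0.60; camera, lower, 0.0225, adjusted p = 0.698 with an estimated correlation), with a median of −0.23 and a mean of 0.14. Ribosome biogenesis rose in 1 of 31 and fell in 2 (0 and 2 adjusted over the list alone; nucleophosmin, Npm1, −0.54; 0.00998, adjusted p = 0.719 with an estimated correlation), and glycolysis fell in 2 of 18 (0 adjusted over the list alone; 0.00249, adjusted p = 0.654 with an estimated correlation).

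Smaller lists in the same comparison were naive and memory genes (4 higher and 2 lower of 27, the same adjusted over the list alone; Myb 0.38; camera 0.0298, adjusted p = 0.717 with an estimated correlation), cytokine receptors and STAT5 feedback (1 and 5 of 24), inhibitory and receptor-induced genes (3 and 5 of 29), TGF-β targets (3 and 1 of 17), YAP and TAZ targets (4 and 0 of 10), other DOCK exchange factors (3 and 0 of 9; Dock2 0.29), hypoxia (1 and 1 of 25), ESCRT (1 and 0 of 23) and sex-linked transcripts (3 and 0 of 5; Uty 0.39). Adjusted over the list alone the last 8 had 1 and 5, 5 and 5, 3 and 1, 5 and 0, 3 and 0, 0 and 0, 1 and 0, and 3 and 0 by edgeR. In media, camera placed heat shock (7.89e-05), cytotoxic effectors (4.88e-05), neutrophil and mast cell markers (3.64e-06, few reads), ribosome biogenesis (1.45e-05), mitochondrially encoded transcripts (0.000137), oxidative phosphorylation (0.00648), cholesterol synthesis (0.0225) and antioxidant genes (0.0118) higher in KO cells. It placed naive and memory genes (1.86e-05), G2 and M genes (1.09e-05), NF-κB and DNA sensing genes (0.0136), interferon-stimulated genes (0.0181) and cytokine receptors (0.0298) lower. With an estimated correlation the adjusted p of these lists lay between 0.259 and 0.719.

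Markers of other cell types rose in KO gel against media in 3 of 11 B cell genes, 4 of 8 CD4 and regulatory T cell genes (camera 0.0206, adjusted p = 0.259 with an estimated correlation; Ikzf2 0.64, from a lower level in KO than in WT media, −0.45, and Ctla4 0.44, which activated CD8 cells also express), 3 of 13 macrophage genes, 3 of 12 NK genes, 4 of 6 neutrophil and mast cell genes (0.00432, adjusted p = 0.52 with an estimated correlation), 4 of 10 erythroid and platelet genes (0.00368, adjusted p = 0.376 with an estimated correlation; Itga2b 1.55) and 1 of 5 stromal genes, with 1 lower (Vim −0.46). Adjusted over the list alone 5, 5, 3, 3, 5, 6 and 1 were higher. Most of these had few reads: Mpo of neutrophil precursors had 2 counts in WT media, 28 in KO media, 3 in WT gel and 137 in KO gel, and the invariant chain gene Cd74 stood at 3.61 CPM in KO gel and 1.87 in WT gel. Cd4 stood at 5.29 and 2.39 CPM. The abundant neutrophil transcripts S100a8 and S100a9 stood at 0 CPM in KO gel.

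The genes called between KO and WT in media hold candidates for an inherited difference between the mouse lines. The transhydrogenase gene Nnt is deleted in part in the substrain C57BL/6J and intact in others, so its higher level (1.23) could come from the strain background of the KO line; no label gives the strain. A further candidate is the stretch of similar gene copies on chromosome 14 (69277601 to 69683286), which holds 8 of the 36 called genes. All 8 were lower in KO, by −0.54 to −8.83 in media and by −0.80 to −7.19 in gel. A difference in the number of copies was not tested. Of the 36 called genes 77.8% were also called in gel in the same direction, which an inherited difference needs. A direct effect of Dock8 would give that share too, so these cannot be told apart by it. A passenger segment within 10 Mb of Dock8 is argued against as the source of these calls, with 0% of the called genes with a position there (0 of 33, edgeR calls, among 91 tested genes), but Tmem223 (from 8770996) and Plce1 (from 38481109), called on the same chromosome and named after their values were seen, lie outside that window, so a wider segment was not excluded. For the call count itself, 1 of 10 splits gave as many calls (36; highest other 0), too few splits for a share under 0.05, and without the libraries rich in ribosomal RNA 19 genes were called.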
